A study of Homo sapiens with 12 samples.

How the data were processed

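Gene expression was measured by sequencing of total RNA in 12 libraries from H9, an established human embryonic stem cell line that had been differentiated toward hepatocytes. The libraries formed 6 groups of 2, given by day 7 or day 19 of differentiation and by treatment with 0.1% DMSO as the control, 30 nM T3 (triiodothyronine, the more potent thyroid hormone at its nuclear receptors) or 30 nM T4 (thyroxine, which carries 1 more iodine than T3). Per the labels, cells of day 7 were hepatoblasts and cells of day 19 hepatocytes. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Nor do they say when hormone was added or how long cells were exposed. Treatment before the cells became endoderm thus cannot be told from later treatment. A DMSO share is given for control cells alone, so the vehicle of the hormone-treated cells is not stated.

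The deposited files held, for each library, a transcript table with expected counts and FPKM values. The authors named the hg38 build and the tools HISAT, Bowtie2 and RSEM without versions, and transcripts carried RefSeq accessions with Entrez gene numbers. Expected counts, the deposited unit used here, are the reads or fragments that RSEM assigns to each transcript, with shared reads divided in proportion, and are not normalised. The deposited FPKM values are scaled by the authors to transcript length and to mapped reads, and were used only as an alternative unit. Only transcripts with an FPKM of at least 0.01 were listed, so a gene at 0 was at or near 0 in that library. The strand of counting was not given, so genes that overlap on opposite strands could not be separated with certainty. Overlaps are marked below for some genes only. Others that overlap another gene include the receptor genes THRA and THRB, and IGF2, DDIT3, KRT8 and KRT18.

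Expected counts were summed over the transcripts of each gene and rounded to whole numbers with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15. The files held 23922 genes, of which 23801 matched a symbol of the GRCh38 RefSeq annotation by Entrez number and 121 did not. The unmatched genes held 0.103% to 0.145% of the counts of a library. No mitochondrially encoded gene was in the files (0 genes), so the share of mitochondrial reads could not be checked. Total counts were 18363549 to 19306181 per library, and the counting error of a value follows from these totals. A floor of 3 counts over the 2 libraries of a group stands for a group at 0, which corresponds to 0.0722 to 0.091 CPM (counts per 1e+06 counts). Such floors cover counting error only.

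Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr on the 6 groups, which left 18101 genes, and libraries were scaled by TMM. All 12 libraries entered a single quasi-likelihood fit with a mean per group, 6 residual degrees of freedom and no block for the replicate number. The common biological coefficient of variation was 5.42%. A gene was called changed at an adjusted p (Benjamini-Hochberg over all tested genes, two-sided quasi-likelihood F test) of at most 0.05. Standard errors were the absolute log2 fold change divided by the square root of F, and intervals are 95% intervals on 6 residual and the prior degrees of freedom. Levels are TMM-scaled CPM, given as the mean with the SD of 2 libraries. Spread between the libraries of a group was larger than sampling noise in every group: the chi-square per gene was 1.585 to 2.10 at day 7 and 4.954 to 8.618 at day 19. The shared fit therefore overstates the spread at day 7 and understates it at day 19.

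Contrasts were T3 against DMSO and T4 against DMSO on each day, T4 against T3 on each day, DMSO at day 19 against DMSO at day 7, and the difference of each hormone effect between the days. Before the data were examined, 34 gene lists (hormone response, cell types, metabolism, stress and signalling) and the rule for naming genes were fixed, and 33 lists with at least 5 measured members were tested. The list of mitochondrially encoded genes had 0. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists of a contrast, then with a correlation estimated from the data, and with fry, which asks only whether the genes of a list move 1 way. Counts of list members are given over all genes and, where marked, adjusted over the list alone. The naming rule took the 8 genes with the largest and the 8 with the smallest log2 fold change of each comparison that passed the test, reached 1 CPM in a group and had replicates that did not overlap, leaving out symbols starting LOC, LINC or MIR. It added KLF9, THRSP, HR, DIO1, DIO3, THRA, THRB, AFP, ALB, HNF4A, CYP3A4 and CYP7A1, and the 4 members with the smallest p of each list described. Results of some genes within this rule are not reported here. THRSP and CYP7A1 did not pass the expression filter and have no test. Not every gene the rule took is named. Several that it took are read-through or near-identical gene models and are left out.

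Similarity of the T3 and T4 effects of a day, which share the same 2 control libraries, was compared with 20 simulations of unchanged groups set against the same controls. The procedure was tested, without its filter step, on simulated data with known changes. Genes changed 1.5-fold, 2-fold or 4-fold were drawn from those at 1 CPM or more in DMSO of that day. Recovery of genes below that level was not tested. At day 7 the procedure recovered 70.1% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold. Of its calls 2.84% were false. At day 19 it recovered 68.7%, 73.1% and 98.5%, and 28.25% of its calls were false, so adjusted p-values of the day 19 groups are too small on average. Only 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold, and 63 unchanged genes were called at day 19. The share of false calls depends on how many genes are changed, so 28.25% is not an estimate for the real calls. A list raised 1.3-fold was recovered on both days (adjusted p = 4.01e-06 and 0.000143 with an estimated correlation), and camera with the preset correlation called 0 and 1 of the 32 other lists. Genes were simulated independently of each other, so this could not show how the preset correlation fares for lists of correlated genes. With T3 at day 19 the estimated correlations ran from -0.0657 (neuroectoderm and neurons) to 0.812 (cytosolic ribosomal proteins).

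Alternatives fixed before the data were examined were DESeq2 size factors, no filter, a filter of 1 CPM in 4 libraries, the DESeq2 1.42.0 Wald test, limma-trend on log2 of FPKM plus 1, fits on the libraries of a day or of the 2 groups compared, a block for the replicate number within each day, an added minimum of 2-fold, and leaving out each library in turn. A fit without the 10 most abundant genes was added after seeing the data. A smaller pseudocount had been planned for files with FPKM alone and was not run, as counts were deposited. Figures were drawn with matplotlib 3.10.9.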

Results

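Transcript levels were measured in H9-derived cells at day 7 (hepatoblasts) and day 19 (hepatocytes) of differentiation, after 0.1% DMSO, 30 nM T3 or 30 nM T4, with 2 libraries in each of the 6 groups. The series asks which genes respond to thyroid hormones during human hepatocyte development. Each library held 18363549 to 19306181 expected counts over 23922 genes, of which 18101 were tested. The 10 most abundant genes of a library took 5.48% to 5.87% of its counts at day 7, 11.7% and 12.1% in the DMSO libraries of day 19, and 6.93% to 6.94% in the hormone-treated libraries of day 19.

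In DMSO, cells of day 19 expressed liver genes at far higher levels than cells of day 7. AFP, the fetal counterpart of albumin (Entrez gene 174, GRCh38 chromosome 4, 73436221 to 73456174), rose from 133 ± 3.54 to 34200 ± 1790 CPM (SD, n = 2), 257-fold (SE of the log2 fold change 0.174, adjusted p = 3.43e-14). ALB, which encodes albumin, rose from 1.13 ± 0.239 to 19.3 ± 2.09 CPM, and PLG, which encodes plasminogen, rose by a log2 fold change of 7.35. All 25 measured genes of mature hepatocyte secreted proteins rose, 25 adjusted over the list alone, with a median log2 fold change of 4.37 (camera, adjusted p = 0.034 with an estimated correlation). Of the 20 genes of mature hepatocyte enzymes and receptors 19 rose, 19 adjusted over the list alone (adjusted p = 0.0403 with an estimated correlation), among them PCK1 of gluconeogenesis at 10.65 and AGXT at 7.78. Transcripts of undifferentiated and dividing cells fell. LIN28A, a pluripotency factor, went from 1040 ± 9.11 to 28.9 ± 1.06 CPM. Of 19 pluripotency genes 16 fell and 1 rose, the same counts adjusted over the list alone (adjusted p = 0.00599 with an estimated correlation), and of 30 cell cycle genes 27 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.00373). The cell cycle inhibitor CDKN1A rose by 5.78.

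Genes of some other lineages also rose in DMSO between the days. COL1A1, a fibrillar collagen, had a log2 fold change of 4.43 (SE 0.085), and 16 of 19 mesenchymal and stellate cell genes rose, 16 adjusted over the list alone (adjusted p = 0.02 with an estimated correlation). All 9 measured genes of the intestine and pancreas list rose, 9 adjusted over the list alone (adjusted p = 0.032 with an estimated correlation), with CDH17, an intestinal cadherin, at 8.04. The rest of the 17 listed genes were not among the tested genes. A gene silent at day 7 can pass the expression filter through day 19 alone, which favours a rise among those measured. LCT, the intestinal lactase, went from 0.168 ± 0.0339 to 1458 ± 112 CPM. SLC26A3, an anion exchanger of the colon, was at 0 at day 7 and at least 381-fold higher at day 19. Of 11 neuroectoderm and neuron genes, by contrast, 7 fell and 1 rose, the same counts adjusted over the list alone (adjusted p = 0.0403 with an estimated correlation). Camera called neither endothelial cells (6 of 12 higher, 3 lower, also adjusted over the list alone, adjusted p = 0.434) nor blood cells (3 of 9 higher, 4 lower, also adjusted over the list alone, adjusted p = 0.55). Of 23 genes of hormone receptors, transporters and deiodinases 16 rose and 6 fell, the same counts adjusted over the list alone (adjusted p = 0.331 with an estimated correlation). The receptor gene THRB rose by 3.53 and the deiodinase genes DIO1 by 4.17 and DIO3 by 3.77, while the deiodinase gene DIO2 fell by 3.51. The hormone-induced genes KLF9 and HR rose by 2.57 and 4.68. THRA rose by 0.70, while HNF4A, a hepatocyte transcription factor already at 342 ± 0.861 CPM at day 7, fell by 0.55. Of 22 thyroid hormone responsive genes 19 rose and 1 fell, the same counts adjusted over the list alone (adjusted p = 0.02 with an estimated correlation). In all, edgeR's quasi-likelihood test called 13112 genes changed, 6801 higher and 6311 lower, and 6071 of them by at least 2-fold. Of the 33 lists 23 were called and 17 of them held with an estimated correlation. With limma on FPKM the median of all genes shifted by -0.239 and 33.1% of the changed genes were higher, against 51.9%.

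**Figure D1:**
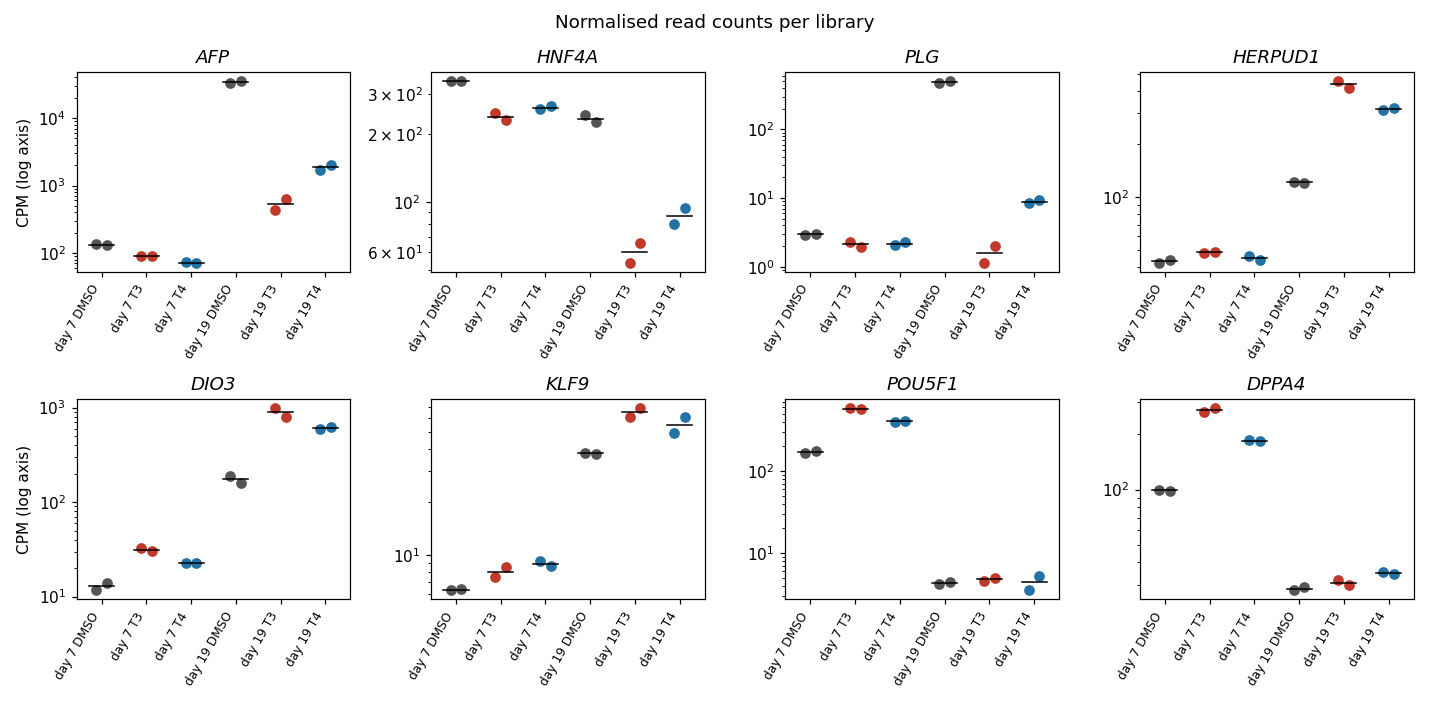
Normalised read counts (CPM, log axis) of 8 genes in each library, by day and treatment. Each dot is 1 of the 2 libraries of a group and the line is the group mean; AFP averaged 34200 CPM in DMSO, 536 with T3 and 1854 with T4 at day 19, and POU5F1 averaged 172, 576 and 405 CPM in DMSO, T3 and T4 at day 7.

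After T3 at day 7, pluripotency genes were higher than in DMSO. POU5F1, a core pluripotency transcription factor (Entrez gene 5460, GRCh38 chromosome 6, 31164337 to 31170682), rose from 172 ± 5.75 to 576 ± 12.3 CPM (SD, n = 2), a log2 fold change of 1.74 (SE 0.0676, adjusted p = 7.92e-10). The DNA methyltransferase gene DNMT3B had a log2 fold change of 1.67, DPPA4 of 1.46 and L1TD1 of 1.39. Of 19 measured pluripotency genes 17 rose and 0 fell, and 18 rose adjusted over the list alone, with a median of 1.70 (adjusted p = 6.88e-05 with an estimated correlation). Cell cycle genes rose by less: 24 of 30, 28 adjusted over the list alone, with a median of 0.39 (adjusted p = 0.00152 with an estimated correlation), including the mitotic kinase genes PLK1 at 0.60 and AURKB at 0.57. In the gluconeogenesis and glycolysis list 11 of 21 genes rose, 11 adjusted over the list alone (adjusted p = 0.00963 with an estimated correlation), and those with the smallest p, PGK1 at 0.53, ALDOA at 0.53 and the glucose transporter gene SLC2A1 at 0.61, act in glucose uptake and glycolysis. Of 14 hypoxia response genes 9 rose, 10 adjusted over the list alone (adjusted p = 0.00892 with an estimated correlation), with PDK1 at 0.77 and ADM at 0.74.

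Some endoderm and early liver genes were lower after T3 at day 7. SOX17 had a log2 fold change of -0.71 (SE 0.0624), GATA4 of -0.62 and FOXA2 of -0.50, all transcription factors of the endoderm. Of 18 definitive endoderm genes 8 fell, and adjusted over the list alone 9 fell and 2 rose (adjusted p = 0.129 with an estimated correlation). Of 20 hepatoblast genes 8 fell and 3 rose, 10 and 3 adjusted over the list alone (adjusted p = 0.304 with an estimated correlation). HNF4A went from 342 ± 0.861 to 238 ± 12.0 CPM, and IGF2, a fetal growth factor of the same list, rose by 0.77. The endothelial cadherin gene CDH5 fell by 1.26, with 8 of 12 endothelial genes lower and 1 higher, also adjusted over the list alone (adjusted p = 0.129 with an estimated correlation). Of the secreted proteins 8 of 25 fell and 1, the complement gene C3 at 1.17, rose, 10 and 2 adjusted over the list alone (adjusted p = 0.538 with an estimated correlation). The hormone-inactivating deiodinase gene DIO3 (Entrez gene 1735, GRCh38 chromosome 14, 101561495 to 101563452) rose from 12.8 ± 1.62 to 31.3 ± 1.67 CPM, a log2 fold change of 1.28. KLF9 stood at 0.34 (SE 0.141, adjusted p = 0.125), THRA at 0.07 (adjusted p = 0.731), DIO1 at -0.25 (adjusted p = 0.562) and ALB at -0.57 (adjusted p = 0.269). The 22 thyroid hormone responsive genes as a list did not pass camera (adjusted p = 0.0596), with 6 higher and 2 lower, the same adjusted over the list alone. By fry the list was higher (adjusted p = 0.00625).

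The quasi-likelihood test called 2891 genes changed by T3 at day 7, 1707 higher and 1184 lower, 424 of them by at least 2-fold. The share that was higher was 59%, against 50.1% with limma on FPKM and 52.4% in a fit of the day 7 libraries alone. Among the genes named by the rule, LNCPRESS2, a long noncoding RNA, had a log2 fold change of 5.51 (SE 0.553) and ALDH1A3, a retinoic acid synthesis gene that overlaps another gene, of 3.76. Camera called 11 lists and 4 held with an estimated correlation. Those lost also included blood cells (3 of 9 lower, 4 adjusted over the list alone, adjusted p = 0.129 with an estimated correlation), neuroectoderm and neurons (3 lower and 1 higher of 11, 4 and 1 adjusted over the list alone, adjusted p = 0.174) and oxidative phosphorylation (6 of 26 higher, 7 adjusted over the list alone, adjusted p = 0.716). The count was 5142 in a fit of the day 7 libraries alone and 1325 to 1476 without any 1 of the 4 libraries. AFP fell by 0.56 (adjusted p = 0.0132), THRB rose by 0.50 (adjusted p = 0.0106) and HR by 1.36 (adjusted p = 0.00978), but AFP did not pass without any 1 of the 4 libraries (adjusted p of 0.0607 to 0.0911), THRB without DMSO replicate 1 (0.0868), T3 replicate 1 (0.0632) or T3 replicate 2 (0.054), and HR without DMSO replicate 2 (0.114) or T3 replicate 2 (0.0977); with limma on FPKM, THRB (0.0653) and HR (0.119) did not pass either.

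After T4 at day 7 the pluripotency genes were also higher than in DMSO. POU5F1 rose to 405 ± 3.59 CPM, a log2 fold change of 1.23 (SE 0.0671, adjusted p = 1.03e-07), and DNMT3B, L1TD1 and DPPA4 had log2 fold changes of 1.14, 0.98 and 0.90. Of 19 pluripotency genes 17 rose and 0 fell, 18 adjusted over the list alone, with a median of 1.20 (adjusted p = 9.72e-05 with an estimated correlation). UTF1, a chromatin factor of embryonic stem cells, rose from 1.59 ± 0.00122 to 10.9 ± 0.496 CPM, and LNCPRESS2 from 0.217 ± 0.238 to 4.50 ± 0.024 CPM. Of 30 cell cycle genes 19 rose, 25 adjusted over the list alone (adjusted p = 0.0015 with an estimated correlation), with AURKB at 0.45. Of 14 hypoxia response genes 8 rose, and adjusted over the list alone 9 rose and 1 fell (adjusted p = 0.0126 with an estimated correlation). In the gluconeogenesis and glycolysis list 9 of 21 genes rose, and adjusted over the list alone 11 rose and 1 fell (adjusted p = 0.0306 with an estimated correlation); the median was 0.27 and the mean -0.0076.

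SOX17, at -0.51, and CDH5, at -0.88, were lower after T4 at day 7. Of 18 definitive endoderm genes 7 fell, 7 adjusted over the list alone (adjusted p = 0.122 with an estimated correlation), of 20 hepatoblast genes 7 fell and 1 rose, 10 and 2 adjusted over the list alone (adjusted p = 0.0791 with an estimated correlation), and of 12 endothelial genes 8 fell, 8 adjusted over the list alone (adjusted p = 0.0791 with an estimated correlation). AFP fell from 133 ± 3.54 to 71.8 ± 0.797 CPM, a log2 fold change of -0.89 (adjusted p = 0.00156). DIO3 rose to 22.7 ± 0.0521 CPM, a log2 fold change of 0.82 (adjusted p = 0.00272). Values that did not pass were 0.35 for THRB (adjusted p = 0.111, but 0.0348 with the day 7 libraries alone), 0.82 for HR (adjusted p = 0.185), 0.02 for THRA (adjusted p = 0.964) and -1.20 for ALB (adjusted p = 0.0637, but 0.0387 with the day 7 libraries alone). Of the 22 thyroid hormone responsive genes 3 were higher, and adjusted over the list alone 5 were higher and 2 lower (camera, adjusted p = 0.12). By fry the list was higher (adjusted p = 0.0483). The test called 1162 genes, 706 higher and 456 lower, 164 by at least 2-fold. The share that was higher was 60.8%, against 53.5% with limma on FPKM and in a fit of the day 7 libraries alone. Camera called 14 lists, of which 4 held with an estimated correlation. The count was 3243 in a fit of the day 7 libraries alone and 370 to 406 without any 1 of the 4 libraries. HNF4A, at -0.39 (adjusted p = 0.0112), and KLF9, at 0.49 (adjusted p = 0.0495), did not pass without any 1 of the 4 libraries (0.0826 to 0.126 for HNF4A and 0.154 to 0.252 for KLF9), KLF9 did not pass without a filter (0.0662) or with limma on FPKM (0.13) and was at 0.05 without the 10 most abundant genes, and DIO3 did not pass without DMSO replicate 1 (0.0513).

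T3 and T4 were compared directly at the same dose and day. At day 7 the pluripotency genes were lower with T4 than with T3: NANOG, a core pluripotency factor, was at 8.59 ± 0.958 CPM with T4 and 19.7 ± 0.805 with T3, a log2 difference of -1.20 (95% interval -1.49 to -0.90, adjusted p = 0.000658), and DPPA4 differed by -0.56 (interval -0.67 to -0.45). Of 19 pluripotency genes 8 were lower and 0 higher, 12 adjusted over the list alone, with a median of -0.53 (adjusted p = 0.000664 with an estimated correlation). IGF2 differed by -0.84 (SE 0.0711). Cell cycle genes had a median of -0.07 (1 of 30 lower, 2 adjusted over the list alone, adjusted p = 0.0361 with an estimated correlation), and gluconeogenesis and glycolysis genes a median of -0.12 (0 of 21 lower, 2 adjusted over the list alone, adjusted p = 0.0361 with an estimated correlation), or -0.11 with the gene at 0 in a group set to its bound. No difference passed for KLF9 at 0.15 (interval -0.13 to 0.44), HNF4A at 0.13 (-0.05 to 0.31), THRB at -0.15 (-0.40 to 0.09) and HR at -0.54 (-1.14 to 0.07). DIO3 at -0.46 (-0.73 to -0.19, adjusted p = 0.233) passed with the DESeq2 test (0.0187) and in a fit of the day 7 libraries alone (0.00372), and AFP at -0.33 (-0.64 to -0.03, adjusted p = 0.659) in that fit (0.000432). The test called 66 genes, 7 higher with T4 and 59 lower, 17 by at least 2-fold, and camera 8 lists, of which 3 held with an estimated correlation. The count was 397, with 35% higher, in a fit of the day 7 libraries alone and 19 to 24 without any 1 of the 4 libraries.

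After T3 at day 19, liver genes were far lower than in DMSO. AFP fell from 34200 ± 1790 to 536 ± 150 CPM (SD, n = 2), a log2 fold change of -6.00 (SE 0.159, adjusted p = 1.66e-12). PLG (Entrez gene 5340, GRCh38 chromosome 6, 160702193 to 160754097) fell from 487 ± 29.2 to 1.59 ± 0.635 CPM, a log2 fold change of -8.25 (SE 0.121). AHSG, encoding the plasma protein fetuin-A, had a log2 fold change of -7.54, the angiotensinogen gene AGT of -4.39, the apolipoprotein gene APOA1, which overlaps an antisense gene, of -4.18, and ALB of -3.95. SERPINA7, which encodes thyroxine-binding globulin, was at 63.1 ± 2.17 CPM in DMSO and at 0 in both T3 libraries, at least 713-fold lower. All 25 measured secreted protein genes fell, 25 adjusted over the list alone, with a median of -3.71 (adjusted p = 0.0287 with an estimated correlation). HNF4A fell from 233 ± 11.9 to 60.05 ± 8.71 CPM, a log2 fold change of -1.96. Of 20 hepatoblast genes 13 fell and 3 rose, 13 and 4 adjusted over the list alone (adjusted p = 0.084 with an estimated correlation).

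Of 20 mature hepatocyte enzyme and receptor genes 16 fell and 1 rose with T3 at day 19, 16 and 1 adjusted over the list alone (adjusted p = 0.0364 with an estimated correlation), including CPS1 of the urea cycle at -4.12 and AGXT at -3.80. In the gluconeogenesis and glycolysis list 13 of 21 genes fell and 4 rose, 13 and 5 adjusted over the list alone (adjusted p = 0.0349 with an estimated correlation), including FBP1 at -4.11 and PC at -1.64, both genes of glucose synthesis. Of 25 cholesterol synthesis and uptake genes 21 fell, 21 adjusted over the list alone (adjusted p = 0.0287 with an estimated correlation), with MSMO1 at -2.30 (SE 0.0787). Of 20 fatty acid and triglyceride synthesis genes 15 fell and 1 rose, 16 and 1 adjusted over the list alone (adjusted p = 0.0347 with an estimated correlation), with the triglyceride synthesis genes DGAT2 at -4.71 and DGAT1 at -1.95. Fatty acid oxidation and ketogenesis (18 of 23 lower, 3 higher, also adjusted over the list alone) and bile acid synthesis and transport (12 of 16 lower, 1 higher, also adjusted over the list alone) both had an adjusted p = 0.141 with an estimated correlation. Camera did not call drug metabolism and transport (13 of 25 lower, 5 higher, also adjusted over the list alone, adjusted p = 0.119) or oxidative phosphorylation (10 of 26 lower, 1 higher, also adjusted over the list alone, adjusted p = 0.282).

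HERPUD1, a gene of endoplasmic reticulum stress, rose with T3 at day 19 from 122 ± 1.11 to 438 ± 27.7 CPM, a log2 fold change of 1.85 (SE 0.0577, adjusted p = 4.99e-12), and the stress transcription factor genes DDIT3 and ATF4 had log2 fold changes of 1.89 and 1.05. Of 17 unfolded protein and amino acid stress genes 16 rose, 16 adjusted over the list alone (adjusted p = 0.102 with an estimated correlation). Of 12 heat shock genes 9 rose, 9 adjusted over the list alone (adjusted p = 0.0364 with an estimated correlation), with HSPB1 at 1.72. Of 16 interferon response genes 15 rose, 15 adjusted over the list alone (adjusted p = 0.267 with an estimated correlation), with MX1 at 2.25 and IRF7 at 1.89. Of 15 immediate early genes 9 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.142 with an estimated correlation), and of 13 metallothionein and oxidative stress genes 6 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.254 with an estimated correlation). NUPR1, a stress-induced chromatin protein gene, rose from 7.76 ± 0.614 to 320 ± 2.39 CPM, a log2 fold change of 5.36.

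Markers of other cell types moved apart with T3 at day 19. COL1A1 fell from 2391 ± 72.8 to 593 ± 81.5 CPM and the collagen cross-linking enzyme gene LOX fell by 3.26. In the mesenchymal list 13 of 19 genes were lower and 3 higher, the same adjusted over the list alone (adjusted p = 0.141 with an estimated correlation). The cholangiocyte genes SPP1 and KRT7 rose by 2.65 and 1.60, while the list held 6 higher and 7 lower of 16, 8 and 7 adjusted over the list alone (camera, adjusted p = 0.0875). Of the thyroid hormone genes, DIO3 rose from 175 ± 21.6 to 886 ± 138 CPM, a log2 fold change of 2.34 (SE 0.102), and KLF9 from 37.9 ± 0.533 to 64.8 ± 5.15 CPM, a log2 fold change of 0.78 (adjusted p = 4.19e-06). SLC7A8, an amino acid and hormone transporter gene, rose by 2.34. DIO1, which activates T4, fell by 1.29, THRA by 0.85 and THRB by 0.40. HR stood at -0.37 (adjusted p = 0.0512, but 0.0478 with the filter of 1 CPM and 0.0499 without the 10 most abundant genes) and CYP3A4 at 0.49 (adjusted p = 0.385). Of the 22 thyroid hormone responsive genes 8 rose and 10 fell, 9 and 12 adjusted over the list alone; median and mean were -0.21 and -0.07 while camera's direction was up (adjusted p = 0.709). The quasi-likelihood test called 9472 genes, 4538 higher and 4934 lower, 2987 by at least 2-fold. Camera called 14 lists, of which 6 held with an estimated correlation. The share of changed genes that were higher was 47.9%, against 52.7% with DESeq2 size factors, 53.5% with the DESeq2 test and 56.5% with limma on FPKM. Which direction held more genes thus depended on the scaling. In simulated day 19 data with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold, 63 unchanged genes were called, 28.25% of the calls. That share cannot be carried over to the 9472 calls here, which far outnumber the genes changed in the simulation.

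**Figure D2:**
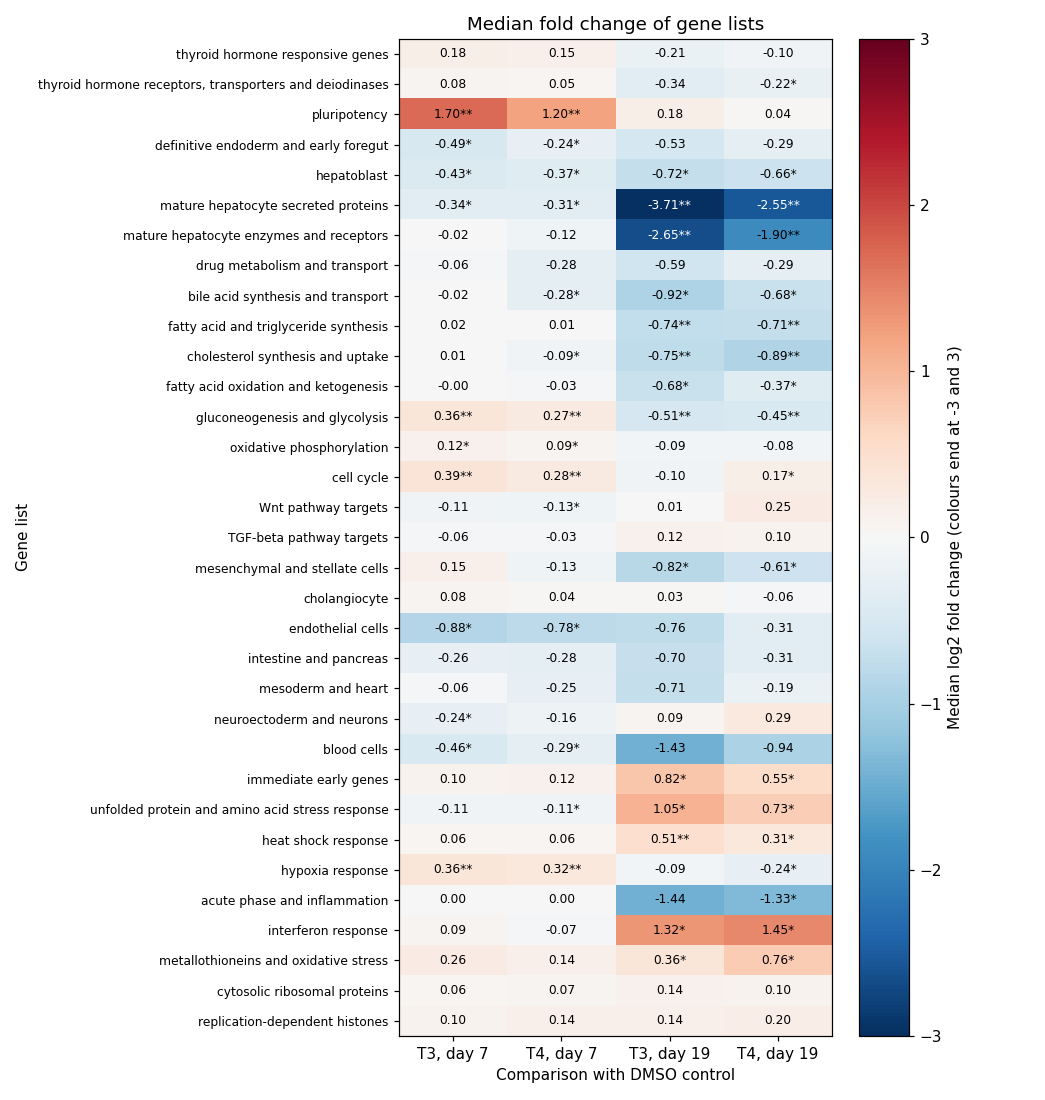
Median log2 fold change (colour) of each fixed gene list for T3 and T4 against DMSO at days 7 and 19. A star marks a list with a camera adjusted p of at most 0.05 and a double star a list that also held with an estimated correlation; secreted proteins had medians of -3.71 with T3 and -2.55 with T4 at day 19, and pluripotency genes 1.70 and 1.20 at day 7.

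After T4 at day 19, liver genes were lower than in DMSO. AFP fell to 1854 ± 238 CPM, a log2 fold change of -4.21 (SE 0.145, adjusted p = 5.3e-11), and PLG, AHSG and ALB had log2 fold changes of -5.78, -6.30 and -2.77. SERPINA7 fell from 63.1 ± 2.17 to 0.313 ± 0.12 CPM. F13B, a subunit of coagulation factor XIII, was at 3.28 ± 0.864 CPM in DMSO and at 0 with T4, at least 38.3-fold lower. Of 25 secreted protein genes 24 fell, 24 adjusted over the list alone, with a median of -2.55 (adjusted p = 0.0151 with an estimated correlation), and HNF4A fell by 1.42. Of 20 enzyme and receptor genes 16 fell and 1 rose, 17 and 1 adjusted over the list alone (adjusted p = 0.0491 with an estimated correlation), with CPS1 at -3.83. All 25 cholesterol genes fell, 25 adjusted over the list alone (adjusted p = 0.0093 with an estimated correlation), with MSMO1 at -2.12 and DHCR7 at -1.02. Among 20 fatty acid and triglyceride synthesis genes 16 fell, 16 adjusted over the list alone (adjusted p = 0.0093 with an estimated correlation), with DGAT2 at -3.38 and the desaturase gene FADS2 at -1.27. In the gluconeogenesis and glycolysis list 15 of 21 fell and 3 rose, the same adjusted over the list alone (adjusted p = 0.0157 with an estimated correlation). Of 20 hepatoblast genes 12 fell and 2 rose, 12 and 3 adjusted over the list alone (adjusted p = 0.11 with an estimated correlation).

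HERPUD1 rose by 1.38 with T4 at day 19 and PSAT1, a serine synthesis gene, by 1.59, with 15 of 17 unfolded protein and amino acid stress genes higher, 15 adjusted over the list alone (adjusted p = 0.121 with an estimated correlation). MX1 rose by 2.33 and IFI6 by 1.43, with 15 of 16 interferon genes higher, 16 adjusted over the list alone (adjusted p = 0.149 with an estimated correlation). HMOX1, the heme oxygenase of oxidative stress, rose by 1.52, with 11 of 13 metallothionein and oxidative stress genes higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.149 with an estimated correlation). HSPB1 rose by 1.43, with 9 of 12 heat shock genes higher, 9 adjusted over the list alone (adjusted p = 0.0554 with an estimated correlation). COL1A1 fell by 1.26 and LOX by 3.08, with 11 of 19 mesenchymal genes lower and 3 higher, 12 and 3 adjusted over the list alone (adjusted p = 0.155 with an estimated correlation). DIO3 rose to 608 ± 24.2 CPM, a log2 fold change of 1.80 (SE 0.101), KLF9 by 0.54 and SLC7A8 by 1.62, while HR fell by 0.80, THRA by 0.83 and DIO1 by 0.75. THRB stood at -0.14 (adjusted p = 0.152, but 0.00492 without DMSO replicate 2) and CYP3A4 at -0.02 (adjusted p = 0.979). Of the 22 thyroid hormone responsive genes 6 rose and 8 fell, 7 and 9 adjusted over the list alone (camera, adjusted p = 0.999). The quasi-likelihood test called 7753 genes, 3793 higher and 3960 lower, 1955 by at least 2-fold. Camera called 18 lists, of which 5 held with an estimated correlation. The share of changed genes that were higher was 48.9%, against 51.1% with DESeq2 size factors, 51% with the DESeq2 test and 66.6% with limma on FPKM.

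At day 19 liver genes were higher with T4 than with T3. PLG was at 8.88 ± 0.619 CPM with T4 and 1.59 ± 0.635 with T3, a log2 difference of 2.48 (95% interval 2.08 to 2.87, adjusted p = 1.96e-06), and AFP differed by 1.79 (1.51 to 2.08), APOA1 by 1.63 and HNF4A by 0.53 (0.33 to 0.73). SLC22A7, an organic anion transporter gene of the liver, differed by 2.51. Of 25 secreted protein genes 20 were higher with T4 and 0 lower, 23 adjusted over the list alone (adjusted p = 0.0834 with an estimated correlation). Of 20 enzyme and receptor genes 9 were higher, 10 adjusted over the list alone (adjusted p = 0.216 with an estimated correlation), with FBP1 at 1.69. Stress genes were lower with T4: HERPUD1 differed by -0.47 and DDIT3 by -0.80, with 13 of 17 unfolded protein and amino acid stress genes lower, 14 adjusted over the list alone (adjusted p = 0.216 with an estimated correlation). Of 12 heat shock genes 8 were lower, 9 adjusted over the list alone (adjusted p = 0.0834 with an estimated correlation), with DNAJB1 at -0.32. Of 30 cell cycle genes 12 were higher and 3 lower, 14 and 4 adjusted over the list alone (adjusted p = 0.0834 with an estimated correlation), with CCNB2 at 0.62. COL1A1 was higher with T4 by 0.75, with 7 of 19 mesenchymal genes higher and 1 lower, 9 and 2 adjusted over the list alone (adjusted p = 0.216 with an estimated correlation). DIO3 was lower with T4 by a log2 difference of -0.55 (-0.75 to -0.34, adjusted p = 0.00155).

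No difference at day 19 passed for THRA at 0.02 (95% interval -0.23 to 0.28), HR at -0.43 (-0.77 to -0.10, adjusted p = 0.0793) and KLF9 at -0.23 (-0.42 to -0.05, adjusted p = 0.0899, but 0.0157 without T4 replicate 2). The test called 2848 genes, 1343 higher with T4 and 1505 lower, 315 by at least 2-fold (245 higher and 70 lower). Camera called 13 lists, of which 0 held with an estimated correlation, while fry called 20. The share of changed genes that were higher was 47.2%, against 62.8% with limma on FPKM, 38.2% with DESeq2 size factors and 36.9% with the DESeq2 test, and the count was 1444 in a fit of the day 19 libraries alone, 1522 without T3 replicate 1, at most 1838 without either T4 library, and 3347 without T3 replicate 2. ALB differed by 1.18 (adjusted p = 0.00798), DIO1 by 0.54 (adjusted p = 0.0132) and THRB by 0.26 (adjusted p = 0.0317), but ALB did not pass without T3 replicate 1 (0.0926) or T4 replicate 1 (0.0715), DIO1 without T3 replicate 1 (0.0883), without T4 replicate 2 (0.094) or in the fit of that day alone (0.0715), and THRB without any 1 of the 4 libraries (0.0812 to 0.141), with DESeq2 size factors (0.0506), the DESeq2 test (0.138), limma on FPKM (0.0518) or the fit of that day alone (0.151).

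**Figure D3:**
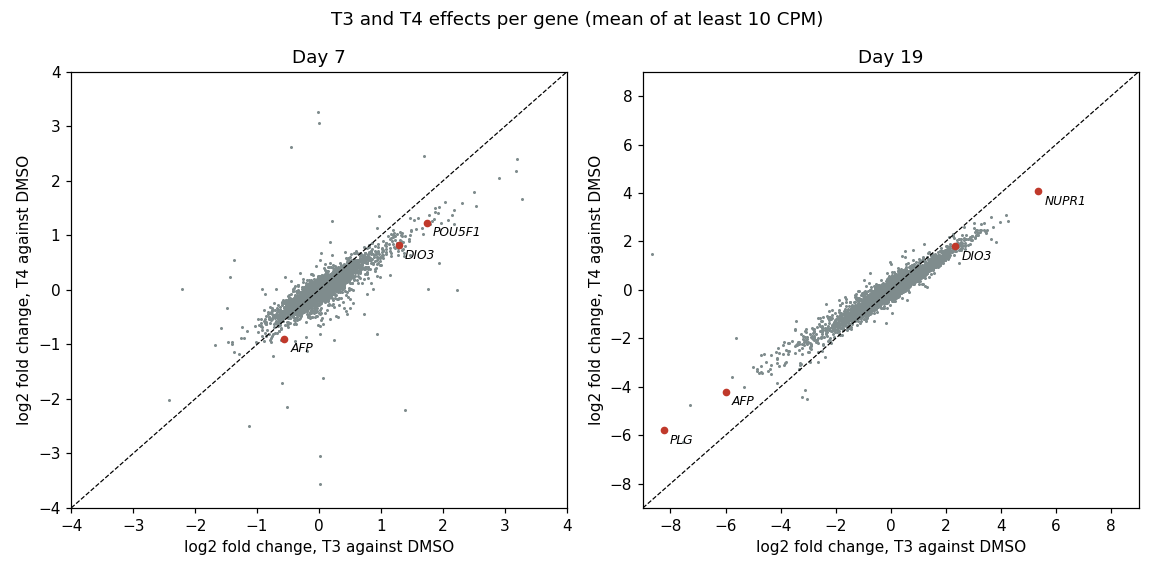
Log2 fold change against DMSO with T4 (vertical axis) and T3 (horizontal axis) of the 10868 genes with a mean of at least 10 CPM, at day 7 and at day 19. Each point is a gene and the dashed line marks equal changes; across these genes the correlation was 0.821 at day 7 and 0.949 at day 19, and both hormones were compared with the same DMSO libraries.

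Genes changed by T3 mostly moved the same way with T4, by less. Of the 424 genes that T3 changed at least 2-fold at day 7, POU5F1 among them, 417 (98.3%) had the same sign with T4 and 405 (95.5%) a smaller change, with a median ratio of log2 fold changes of 0.657. At day 19, 2971 (99.5%) of 2987 had the same sign and 2725 (91.2%) a smaller change, with a median ratio of 0.713. Chosen the other way, T3 had the larger change in 80.5% of the 164 genes that T4 changed at least 2-fold at day 7 and in 77.9% of 1955 at day 19. Both hormones raised 674 genes and lowered 401 at day 7, with 0 opposite, where independent calls would give 66.6 and 29.8. At day 19 they raised 3354 and lowered 3574, with 18 opposite, where independent calls would give 950.9 and 1079.4. Across all tested genes, which are not independent replicates, the correlation of both effects was 0.674 at day 7 and 0.846 at day 19, and simulated unchanged groups against the same controls gave 0.489 and 0.506. The covariance was 0.205 against a simulated 0.0489 at day 7, and 0.722 against 0.0671 at day 19.

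The T3 effect differed between the days for 6873 genes and the T4 effect for 5018, by edgeR's test of the difference itself. AFP is an example, with log2 fold changes of -0.56 and -6.00 with T3 at days 7 and 19, a difference of -5.44 (SE 0.198, adjusted p = 1.92e-10). HR rose with T3 at day 7 and stood lower at day 19, a difference of -1.73 (SE 0.351, adjusted p = 0.00126). Of 1984 genes that T3 changed on both days 1460 moved the same way and 524 the opposite way, and of 725 genes that T4 changed on both days 525 and 200. The difference between days did not pass for KLF9 with T3 at 0.44 (SE 0.168, adjusted p = 0.0531) or with T4 at 0.05 (SE 0.167, adjusted p = 0.857). Because the length of exposure is not given, its part in these differences cannot be told from that of the stage of the cells.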

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

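The tests in this part on secreted proteins and on pluripotency genes were chosen after the results were seen, while the tests on genes at 0 in a group were written before theirs. After the values were seen, the overlaps of C4B_2, which lies on an alternate scaffold, were counted as none, and the pairs in which the loss of a gene moves the sum over overlapping genes were counted.

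The effect of T3 differed between day 19 and day 7 for 6873 genes and the effect of T4 for 5018, by edgeR's quasi-likelihood test of the difference itself. Stage of the cells and length of exposure, which is not given, cannot be told apart here. With T3 the log2 difference, day 19 minus day 7, was -5.44 for AFP, -3.38 for ALB, -1.43 for HNF4A, -1.73 for HR, -1.03 for DIO1, -0.921 for THRA, -0.899 for THRB and 1.06 for DIO3. With T4 it was -3.31 for AFP, -1.57 for ALB, -1.03 for HNF4A, -1.62 for HR, -0.843 for THRA, -0.487 for THRB and 0.974 for DIO3. The median difference over the list was -3.383 with T3 and -2.194 with T4 for secreted proteins, -0.7889 and -0.8251 for fatty acid and triglyceride synthesis, -0.8116 and -0.7579 for cholesterol synthesis and uptake, -0.8851 and -0.5825 for gluconeogenesis and glycolysis, and -0.6521 and -0.5888 for hypoxia response, each also past the threshold with an estimated correlation.

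The fall of secreted protein genes with T3 at day 19 was weighed against 4 explanations. A few abundant genes taking the counts would push all genes the same way. The 10 most abundant genes took 11.7% and 12.1% of the counts in DMSO and 6.94% and 6.93% with T3. If anything, this would raise other genes with T3 and not lower them. With scaling to total counts alone the median of all tested genes was 0.045, a value that those shares left little room to differ from. A plain loss of hepatocyte-like cells in favour of every other type would raise all other markers, but 4 of the 7 lists of other cell types (mesenchymal, intestine and pancreas, mesoderm, blood) had medians below -0.5 and fell by fry. By camera, which sets a list against all other genes, only the mesenchymal list of these 4 was past the threshold (adjusted p = 9.45e-05, 0.141 with an estimated correlation). Intestine and pancreas (adjusted p = 0.093, 0.306 with an estimated correlation), mesoderm (0.094 and 0.368) and blood (0.0761 and 0.184) were not. A loss of hepatocyte-like cells in favour of only some other cell types was not tested and stays open. DMSO libraries that stand apart while T3 and T4 libraries are alike are argued against, because T4 and T3 differed by a median of 1.119 (fry, adjusted p = 0.00164, camera adjusted p = 0.0834 with an estimated correlation). That comparison holds no DMSO library, so deviating DMSO libraries beside a difference between T3 and T4 stay open. A difference between cultures apart from the hormone cannot be told apart from the hormone itself, because the labels do not say which libraries are separate cultures; the libraries of a group differed by a median of at most 0.53, and an effect of the hormone stays open beside it.

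The rise of pluripotency genes with T3 at day 7 was not one of depth, since total counts of T3 and DMSO libraries stood at a ratio of 1.008. Totals were known beforehand and libraries were scaled, so this check could hardly have come out otherwise. DMSO libraries that stand apart while T3 and T4 libraries are alike are argued against by a median difference of T4 from T3 of -0.529, but deviating DMSO libraries beside such a difference stay open. A larger share of cells that stayed undifferentiated, whether by chance or by the hormone, may account for part of it: the SD of the log2 fold changes of the changed members was 1.33 against a median SE of 0.15, but only markers absent from all other cells would have to rise by a common fold, and which ones are absent is unknown here.

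Among genes called changed between groups of the same day, 25 were at 0 in both libraries of 1 group. They stood at 1 CPM or more in the group compared, and 9 of them overlap another counted gene. The comparison of DMSO between the days was not included. For those 9, reads assigned to a neighbour in some libraries cannot be told apart from a change of the gene. Summed over each gene and its overlapping genes, the median absolute log2 fold change was 0.13 over 14 pairs of gene and comparison, but in 12 of these the loss of the gene alone would have moved the sum by less than 0.5. The other 2, singled out after their values were seen, went different ways. For CCDC180, T4 against T3 at day 19, the sum differed by 0.297 where the loss of the gene alone would give 0.527, and its own call ended without T3 replicate 1 (adjusted p = 0.0865), T3 replicate 2 (0.0536) or T4 replicate 1 (0.116). The sum for EIF3CL stayed at 0 with T3 at day 7 against 2.335 CPM in DMSO, all of it from DMSO replicate 1, without which the fitted log2 fold change was 0 (adjusted p = 1, and 0.188 without T3 replicate 1 and 0.18 without T3 replicate 2). Of the 25 genes 36% overlap another gene, against 35.2% of tested genes. Any shared position counted as overlap, small RNA genes included, so equal shares do not show how often reads were exchanged. Several of the 9 are read-through gene models, such as FMC1-LUC7L2 and TMX2-CTNND1, which overlap the genes they join. Overlap cannot account for those of the 25 that overlap no counted gene. The ratio was 1.02, or 1.14 with C4B_2 counted as overlapping. That share decides nothing for the 9 that do overlap. Neither it nor the sum over overlapping genes can show reads exchanged with a near-identical gene elsewhere. EIF3CL, for example, overlaps MIR6862-1 alone. SERPINA7 and F13B, which fell at day 19, overlap none.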

How the results depend on the processing

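The fit without the 10 most abundant genes was chosen after seeing the data, and all other alternatives before. Of 272 values of named genes 247 passed; 19 lost the call with the DESeq2 test, 14 with limma on FPKM, 3 without a filter, 2 with the libraries of a day or pair alone, 1 each with DESeq2 size factors and the block, 1 of the 237 passing values that were tested without the 10 most abundant genes, 0 of the 227 tested with the filter of 1 CPM, and 31 on leaving out at least 1 library. The only named value to lose its direction under these was that of EIF3CL with T3 at day 7, whose fitted values without 1 library ranged from -9.442 to 0, the latter without DMSO replicate 1, the only DMSO library of that day with counts of it. Counts of changed genes stayed within 1.5 times with DESeq2 size factors, either filter, the block, the DESeq2 test, limma on FPKM and without the 10 most abundant genes. In fits of the libraries of a day they were 5142 (T3) and 3243 (T4) at day 7, and 397 and 1444 for T4 against T3 at days 7 and 19, where the spread of a day is its own; such fits give no difference between days. With a minimum of 2-fold, which by construction leaves fewer, they were 424 (T3) and 164 (T4) at day 7, 2987 and 1955 at day 19, 17 and 315 for T4 against T3 at days 7 and 19, 6071 for DMSO between the days, and 2432 (T3) and 1467 (T4) for the difference between days. Without 1 library, assuming that the lone library varies like the other groups, they were 1325 to 1476 (T3) and 370 to 406 (T4) at day 7, 8246 to 8963 and 6121 to 7062 at day 19, 19 to 24 and 1522 to 3347 for T4 against T3 at days 7 and 19, 12029 to 12349 for DMSO, and 5721 to 6921 and 3839 to 4782 for the difference between days. List calls, 101 of 231, were 39 with an estimated correlation, 101 with the block, which lost cell cycle with T4 at day 19 (adjusted p = 0.0517) and gained mesenchymal and stellate cells with T4 at day 7 (0.0392), and 142 with fry. The correlation of T3 and T4 effects was 0.821 at day 7 and 0.949 at day 19 over genes of at least 10 CPM, where simulated unchanged groups with the same controls gave 0.473 and 0.503. Differences between replicates 1 and 2 correlated across genes between groups of a day by -0.065 to 0.04 at day 7 and -0.297 to 0.361 at day 19. No pairing of libraries by number was seen at day 7. At day 19 the values were 0.361 for DMSO and T3, 0.172 for T3 and T4 and -0.297 for DMSO and T4. A pairing of some groups of that day stays open. Apart from the settings explained, the cause of a change was not tested. A pseudocount of 0.1 was not run. At these depths genes near the floor of 3 counts allow only lower bounds of a fold.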

Other observations

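The test of a developmental delay in this part was written before its result was seen. Endothelial markers split with the hormones at day 19. ENG, a co-receptor for transforming growth factor beta that overlaps another gene, rose with T3 from 69.9 ± 0.896 to 489 ± 17.7 CPM (SD, n = 2), a log2 fold change of 2.81, and CDH5 rose by 1.70, while PECAM1, another endothelial adhesion gene, fell by 1.62. Of 12 endothelial genes 2 rose and 7 fell, the same adjusted over the list alone, with a median of -0.76 although camera's direction was up (adjusted p = 0.733). With T4, 2 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.476, 0.739 with an estimated correlation). The neuronal tubulin gene TUBB3 rose with T3 by 1.98 and MAP2 by 1.96, with 3 of 11 neuroectoderm genes higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.194). The keratin genes KRT18 and KRT8, which overlap each other, rose with T3 by 1.59 and 1.25. Both are in the definitive endoderm list, in which 3 of 18 genes were higher and 11 lower with T3, also adjusted over the list alone. Its median was -0.53 (fry, adjusted p = 0.00559, camera adjusted p = 0.331, 0.674 with an estimated correlation). Between the days in DMSO, the interferon genes IFI6 and MX1 rose by 6.23 and 4.46, with 14 of 16 interferon genes higher, 14 adjusted over the list alone (adjusted p = 0.355 with an estimated correlation). All 25 cytosolic ribosomal protein genes fell, 25 adjusted over the list alone, with RPL4 at -0.86 (adjusted p = 0.377 with an estimated correlation).

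Liver genes that rose in DMSO between day 7 and day 19, such as AFP, were lower with hormone at day 19, so a candidate explanation is that treated cells stayed at an earlier point of a common course. Of the 1772 genes that rose at least 4-fold in DMSO, 883 (49.8%) fell with T3 at day 19 and 776 (43.8%) with T4, against 25.3% and 20.1% of the other genes, but 501 (28.3%) rose with T3 and 450 (25.4%) with T4, against 25.2% and 20.7%. The same course would leave the genes that fell in DMSO higher, but of 778 genes that fell at least 4-fold 122 (15.7%) rose with T3 at day 19 and 118 (15.2%) fell, against 25.2% and 25.3% of the other genes. The share that rose met the bound set beforehand. Fewer of these genes than of the others were called in either direction, however, so the low share is no evidence on its own. A delay of the whole course would move them mainly up, but nearly as many fell as rose. That balance was counted with TMM scaling alone. Over all genes called with T3 at day 19, 47.9% were higher with TMM and 52.7% with DESeq2 size factors. A simple delay of the whole course is thus argued against for T3 under TMM scaling only, and on that balance alone. A delay of part of it stays open: the pluripotency list, which fell in DMSO, held 7 higher and 1 lower of 19 with T3 at day 19, 5 and 1 adjusted over the list alone, with a median of 0.18 (fry, adjusted p = 4.41e-05, camera adjusted p = 0.142, 0.306 with an estimated correlation). With T4, for which no bound had been set, 121 (15.6%) rose and 66 (8.5%) fell, against 20.7% and 20.1% of the other genes. The share that rose was as low, but more of them rose than fell, so a delay stays open for T4. The effects share the DMSO libraries of day 19: the correlation across genes of the T3 effect with the change between the days was -0.209, and simulated unchanged groups gave -0.105.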
